A study of Arabidopsis thaliana with 12 samples.

How the data were processed

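The series compared roots of Col and erf114 seedlings on MS or MeJA, with 4 groups of 3 libraries taken from the sample titles. Per the labels' protocols, seeds were kept cold on MS plates and grown for 5 days at 22 °C, MeJA was applied at 15 µM, total RNA was extracted with a column kit, and the transcriptome was sequenced. The series' design text gives 50 µM, and the titles give 3 h. The aligner, the counting tool and the genome build are not given in the sources used here.

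The authors deposited 1 table per library with estimated read counts, TPM and FPKM for each gene. Per the file headers, the count column holds read counts, and 1.542 to 1.718% of the values in a library were fractional, so they were treated as estimated counts and rounded to whole numbers. The deposited TPM values (transcript levels scaled to a fixed library total) were used only to find the smallest value listed, which was 0.01 in every library. The deposited FPKM values (fragments scaled by gene length and library total) were used for the filter, for levels and for the alternatives on a log scale. The deposited tables list only genes above a minimum, so a gene missing from a library was set to 0. All entries were mRNA genes and no organelle gene was listed. All 23719 gene identifiers matched TAIR10.1, and symbols and coordinates are from that match. No column of another sample was present.

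Totals ran from 20546417 to 20897031 estimated counts per library. At this depth, and with a biological coefficient of variation of 17.9%, small differences and genes of few counts could not be resolved. Intervals and floors cover counting error only. A fold against a group at 0 was set against a floor of 3 counts per library and is a lower bound, and 95% intervals of count ratios are exact conditional binomial intervals on group sums. No replicate pair matched within sampling noise, since the chi-square per gene was 7.1 to 61.3.

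The test used R 4.3.3 and edgeR 4.0.16, with TMM factors on the rounded estimated counts, FPKM of at least 1 in at least 3 libraries (18326 genes), a mean for each of the 4 groups, a common estimate of spread with 8 residual degrees of freedom, and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The design fixed before the data were examined had assumed FPKM tables and limma and named edgeR for the case that counts were present; counts were present, so limma 3.58.1 on log2(FPKM + 1) became an alternative. The SE of a log2 fold change is its size divided by the root of the F statistic. This is approximate for genes of few counts. The contrasts were MeJA against MS in each genotype, erf114 against Col on each medium, and their interaction.

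The genes named are, for each contrast, the 10 called genes with the largest rise and the 10 with the largest fall, among those with a mean FPKM of at least 5 in the higher group and no overlap between replicates (for the interaction, at least 5 in any group), with ERF114, ERF115, ERF109, JAZ8 and members of the lists. In the closing section, genes outside this rule were chosen after their values were seen. There were 29 lists of 283 genes in all, fixed before the data were examined. They covered JAZ repressors, JA biosynthesis, JA catabolism, JA receptor and MYC/JAM factors, MYC-branch and ERF-branch defence, ERF group X, regeneration, tryptophan and auxin biosynthesis, auxin response, indole and aliphatic glucosinolates, triterpene clusters, PYK10 and ER bodies, camalexin, flavonoids, ethylene, salicylic acid, touch and stress, the stem cell niche, mitosis, root hairs, endodermis, root cap, xylem, phloem, iron uptake, shoot photosynthesis and seed storage. List genes whose reference symbol differed (JOX3 as JRG21, CHI as TT5, ERF109, FIT and several unnamed genes) were kept under the known synonym, although the plan had been to drop them. DAD1, ERF110, CYP71A13 and MYC5 were not analysed here. Camera was run on the 28 lists with at least 3 tested genes, with a preset correlation of 0.01 and with an estimated correlation, and adjusted over the lists of a contrast. Of 47 list calls with the preset value, 17 held with the estimated one.

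The response score of a library is the mean log2(FPKM + 1), signed by direction, of genes that moved by at least 1 between MS and MeJA in the mean of both genotypes. Its genotype difference was tested by an exact 2-sided permutation of genotype within treatment (400 permutations). Replicate numbers were checked for pairing from the correlation of deviations from the group means, with 0.1 as the minimum in every pair. MS and MeJA libraries of Col paired by that rule (0.43, 0.41 and 0.23), as did Col and erf114 on MS (0.21, 0.19 and 0.29). The other contrasts did not. The labels do not say what a number shares. With the block, 4405 genes were called for MeJA in Col and 4 for the genotypes on MS.

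Alternatives fixed beforehand were a pseudocount of 0.1 (with limma), no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile scaling (with limma), the replicate block, only the groups compared, other variance models, a score minimum of 0.5, an estimated list correlation and leaving out each library. Alternatives added after the data were seen were DESeq2 1.42.0, limma on log2(FPKM + 1), removal of a trend with transcript length and GC content, leaving out both Col MS replicate 1 and erf114 MeJA replicate 3, and the block combined with other choices.

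The gene tests, camera with the preset correlation, the length and GC trend and the score were tested on simulated counts for the 18326 genes. For the gene tests 200 genes were changed, far fewer than MeJA changed in the real data. Counts were drawn for each gene alone, with the spread that edgeR had estimated. Structure shared between genes within a library was thus not simulated, and the rates below may not hold for the real libraries. The pairing, the splits and the tests of explanations were not simulated. edgeR recovered 55% of 2-fold and 95% of 4-fold changes for MeJA in Col, 68% and 99% for MeJA in erf114, 62% and 96% for the genotypes on MS, 60% and 97% on MeJA, and 38% and 84% for the interaction, with 2.3 to 6.8% of calls false. DESeq2 made 26 to 44 false calls in the same data, against 4 to 11 for edgeR. With equal responses the score difference was 0.01 (exact permutation p = 0.32).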

Results

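RNA sequencing was used to measure transcript levels in roots of 5-day-old Arabidopsis thaliana seedlings of the reference accession Col and of the erf114 mutant. Roots were taken from mock plates (MS medium) or 3 h after addition of methyl jasmonate (MeJA), the volatile ester of the wound hormone jasmonate (JA). Each of the 4 groups held 3 libraries, 12 in all. The MeJA dose was 15 µM in the treatment protocol and 50 µM in the series' design text, so the dose is not settled. Each library held 20546417 to 20897031 estimated counts over 21209 to 21845 listed genes, and 18326 genes entered the tests. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless camera, a test of gene lists, is named. A value after ± is the standard error (SE) for a log2 fold change and the SD (n = 3) for an FPKM level. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

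ERF114 (AT5G61890, chromosome 5, 24852322 to 24853941 on TAIR10.1) encodes a transcription factor of the ERF family and is the gene mutated in erf114. On MS it was at the limit of detection in both genotypes, with 3 counts over the 3 Col libraries and 2 over the 3 erf114 libraries. On MeJA it reached 2.53 ± 0.41 FPKM in Col (151 counts) and 0.60 ± 0.09 FPKM in erf114 (36 counts). Col libraries thus held 3.87 times as much per unit of depth, with a 95% counting interval of 2.68 to 5.73, and all 3 Col libraries (59, 50 and 42 counts) lay above all 3 mutant libraries (13, 13 and 10). The exact 2-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The edgeR contrast was -1.95 ± 0.39 on the log2 scale, with an adjusted p = 0.071 that missed the threshold. DESeq2 gave an adjusted p = 0.00056 for the same difference. Reads at ERF114 thus remained in the mutant, and the kind and position of the mutation are not given in the sources used here.

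Along the main axes of variation the libraries separated by treatment and, within groups, by library. The first component held 59.4% of the variance and the second 17.1%. Col MS replicate 1 lay at 57.1 on the second component, against -24 and -10.6 for the other libraries of its group, and the erf114 MeJA libraries were spread along it, at 19.4, -22.4 and 48.3. erf114 MS replicate 3 lay at -34.6 on the first component, against -52.6 and -51.4.

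**Figure D1:**
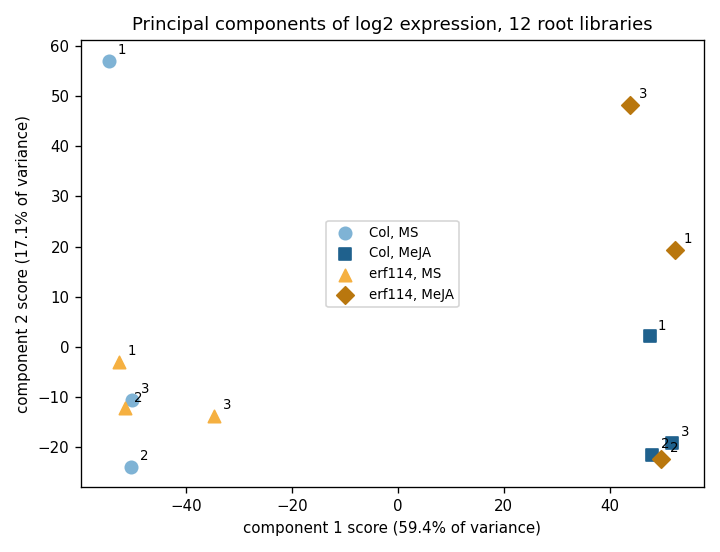
Principal components of the log2 levels of the 18326 tested genes, with component 1 (59.4% of the variance) on the x axis and component 2 (17.1%) on the y axis, 1 point per library, with colour and symbol by group and the replicate number beside it. On component 2 Col MS replicate 1 sits away from the other libraries of its group, and the erf114 MeJA libraries are spread from -22.4 to 48.3.

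MeJA against MS in Col addressed how wild-type roots respond to applied jasmonate, the reference for the role of ERF114 in JA signalling. After 3 h JRG21 (also JOX3, AT3G55970, chromosome 3, 20766735 to 20769410), a jasmonate-inactivating oxygenase, rose by 8.89 ± 0.29 on the log2 scale, from 0.2 ± 0.08 to 93.2 ± 14 FPKM (edgeR adjusted p = 2.8e-09). VSP2 (AT5G24770, chromosome 5, 8500468 to 8502224), a vegetative storage protein and classic jasmonate marker, rose from 1.81 ± 0.13 to 234 ± 24 FPKM, a log2 change of 7.05 ± 0.20 (edgeR adjusted p = 1.1e-09). NRT2:1 (AT1G08090, chromosome 1, 2524023 to 2526322), a high-affinity nitrate transporter of the root, fell from 36.9 ± 2.9 to 1.3 ± 0.35 FPKM, a log2 change of -4.78 ± 0.33 (edgeR adjusted p = 7e-07). Of the 18326 genes, 4026 changed, 1912 higher and 2114 lower. Of these, 1878 changed at least 2-fold, 962 higher and 916 lower, and 6193 genes had an unadjusted p under 0.05.

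The largest rises in Col also included the chlorophyllase CLH1 (8.83 ± 0.41, edgeR adjusted p = 3e-08), the jasmonate oxygenase AT2G38240 (JOX4, 8.58 ± 0.49), AAE12 (8.30 ± 0.40) and BGLU24 (8.19 ± 0.35). AT1G53875, with no counts on MS, was at least 62.2-fold higher on MeJA at 16 ± 3.9 FPKM, taking a floor of 3 counts in each MS library. On the same floor FLP1 was at least 7.28-fold and LCR21 at least 4.32-fold higher, and PGL5 went from 1 to 490 counts. The largest falls, after AT5G44574 (-5.28 ± 0.47) and AT5G01740 (-4.89 ± 0.24), were in NRT2:1, in PHO1;H1 (-4.57 ± 0.29, edgeR adjusted p = 4.1e-07), a homologue of the phosphate exporter PHO1, in the arabinogalactan protein FLA6 (-4.49 ± 0.32), in AT2G10940 (-4.51 ± 1.21), AT3G45160 (-4.37 ± 0.31) and GLP9 (-4.37 ± 0.38), and in the transporter UMAMIT17 (-4.36 ± 0.26). AT4G01060 went from 88 to 3 counts. AT2G10940 was uneven between the Col MS libraries, at 19 ± 21 FPKM on MS and 0.88 ± 0.64 on MeJA.

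Of 13 JAZ repressors, which block JA-responsive transcription until they are degraded, 9 rose over all genes tested and 10 adjusted over the list alone, with a median log2 change of 1.86. JAZ3 rose by 2.31 ± 0.22 (edgeR adjusted p = 1.2e-05), JAZ13 by 5.28 ± 0.62 and JAZ9 by 3.49 ± 0.45. JAZ8 (AT1G30135), named in the series title, stood at 14.9 ± 12.3 FPKM on MS and 42.3 ± 14.9 on MeJA, a log2 value of 1.46 ± 0.82 that did not pass (edgeR adjusted p = 0.23). In a fit chosen after the data were seen, with replicate number as a block and only these 2 groups, JAZ8 passed at 1.77 (edgeR adjusted p = 0.0044). In no other setting did JAZ8 pass in Col. Of 13 tested genes of JA biosynthesis 9 rose, and 10 adjusted over the list alone, among them ACX1 (1.54 ± 0.15, edgeR adjusted p = 1.5e-05), LOX6 (1.79 ± 0.19) and OPR3 (2.08 ± 0.32). Of 9 genes of JA catabolism 7 rose, with the same 7 by count adjusted over the list alone, including the hydroxyjasmonate sulfotransferase ST2A (2.79 ± 0.12, edgeR adjusted p = 2.2e-08) and CYP94B1 (3.80 ± 0.22), which oxidises JA-isoleucine. Camera placed these lists above other genes with a preset correlation, at adjusted p = 8.4e-07 for JAZ, 7e-06 for biosynthesis and 2.8e-31 for catabolism. The adjusted p = 0.12 for JAZ and adjusted p = 0.15 for biosynthesis with an estimated correlation missed the threshold, while catabolism kept its call at 0.0032.

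All 5 tested genes of the MYC-branch, which marks wound and herbivore defence, rose over all genes and adjusted over the list alone, with a median of 6.48 (camera adjusted p = 2.8e-31, and 0.00025 with an estimated correlation). They included VSP1 (5.77 ± 0.21), the tyrosine aminotransferase TAT3 (6.48 ± 0.83) and NAC055 (2.58). Among the 9 tested JA receptor, MYC and JAM genes 4 rose and 1 fell (5 and 1 adjusted over the list alone). NINJA, an adaptor of JAZ repression, rose by 1.11 ± 0.09, the repressor JAM1 by 3.85 ± 0.59 and MYC2, the master regulator of this branch, by 1.07 ± 0.25 (edgeR adjusted p = 0.0082), whereas the corepressor TPL fell by 0.43. The camera call for this list (adjusted p = 0.025) was lost, at adjusted p = 0.15 with an estimated correlation. The ERF-branch went both ways. Of its 7 tested genes 2 rose and 2 fell (3 and 2 adjusted over the list alone), with ORA59, the main activator of that branch, at -3.31 ± 0.31 (edgeR adjusted p = 8.3e-06) and the chitinase PR3 at -0.74. Its median of -0.46 and mean of 0.98 differed in sign, and camera placed it below other genes at an adjusted p = 0.56.

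Of the ERF group X genes, the subfamily of ERF114, ERF115 and ERF109, 5 of 6 tested rose, with 5 adjusted over the list alone (camera adjusted p = 1.2e-07, and 0.018 with an estimated correlation). RAP2.6L rose by 2.15 ± 0.15 (edgeR adjusted p = 6.7e-07), RAP2.6 by 3.02 ± 0.25 and ABR1 by 1.84 ± 0.32. ERF114 went from 3 to 151 counts, a ratio of 53.2 with a 95% counting interval of 17.9 to 261. ERF109 (AT4G34410) stood at 37.7 ± 19.3 FPKM on MS and 64.1 ± 24.4 on MeJA, a log2 value of 0.77 ± 0.75 that did not pass (edgeR adjusted p = 0.49). With the replicate block and only these groups, again a fit chosen after the data were seen, ERF109 passed at 0.91 (edgeR adjusted p = 0.0093). It passed in Col in no other setting. ERF115 (AT5G07310) had 0 to 3 counts in every library, too few to compare. Among 5 regeneration genes 3 rose, and 3 adjusted over the list alone, led by the phytosulfokine precursor PSK5 (2.59 ± 0.26). The camera adjusted p = 0.045 for that list became an adjusted p = 0.12 with an estimated correlation.

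Of 15 indole glucosinolate genes 13 rose and 2 fell, over all genes and adjusted over the list alone, with a median of 1.66 (camera adjusted p = 5.8e-23, and 0.0047 with an estimated correlation). CYP81F4, which modifies indole glucosinolates, rose by 2.20 ± 0.12 (edgeR adjusted p = 1.2e-07) and CYP79B2, which commits tryptophan to the pathway, by 2.02 ± 0.14. Of 13 tryptophan and auxin biosynthesis genes 8 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 1.05 (camera adjusted p = 6.7e-08, and 0.013 with an estimated correlation). ASA1, the first enzyme of tryptophan synthesis, rose by 2.89 ± 0.18 (edgeR adjusted p = 4.2e-07) and TSA1 by 1.95 ± 0.11. Auxin response genes fell. Of 13 tested, 7 fell over all genes and 8 adjusted over the list alone, with a median of -0.95 (camera adjusted p = 0.00017, and 0.013 with an estimated correlation), led by IAA3 (-1.27 ± 0.13) and GH3.6 (-1.69).

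All 7 genes of the PYK10 and ER body list, the beta-glucosidase system of root endoplasmic reticulum bodies, rose over all genes and adjusted over the list alone, with a median of 1.93 (camera adjusted p = 2.6e-21, and 0.00025 with an estimated correlation). BGLU22 rose by 3.31 ± 0.20, the jacalin lectin JAL33 by 2.48 and the regulator NAI1 by 1.93. All 6 tested genes of the thalianol and marneral triterpene clusters rose, and all 6 adjusted over the list alone, with a median of 2.77 (camera adjusted p = 2.7e-22, and 0.0047 with an estimated correlation). Thalianol synthase THAS1 rose by 3.61 ± 0.20 (edgeR adjusted p = 1.4e-07) and marneral synthase MRN1 by 3.88. Aliphatic glucosinolate genes moved apart, with 3 of 9 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.23). SOT17 rose by 2.09 ± 0.12 and CYP83A1 stood at -1.44 ± 0.16. Among 6 tested flavonoid genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with TT5, the chalcone isomerase, at 1.70 ± 0.13 and the flavonol regulator MYB12 at -0.88 ± 0.16 (edgeR adjusted p = 0.0013). The camera adjusted p = 0.045 for that list became an adjusted p = 0.42 with an estimated correlation. Neither of the 2 tested camalexin genes passed.

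Iron uptake genes fell. Of 8 tested, 5 fell over all genes and 6 adjusted over the list alone, with a median of -1.60 (camera adjusted p = 2.8e-06, but adjusted p = 0.093 with an estimated correlation). BHLH100 stood at -4.46 ± 0.39 (edgeR adjusted p = 4.9e-06), the ferric reductase FRO2 at -3.32 ± 0.30 and the iron transporter IRT1 at -3.02 ± 0.28. Of 8 ethylene genes 5 fell and 1 rose, also adjusted over the list alone, with EBF2 at -1.68 ± 0.26 (edgeR adjusted p = 0.00054) and the receptor ETR2 at -0.77 (edgeR adjusted p = 0.021), while camera missed the threshold at adjusted p = 0.052. In the salicylic acid list 1 of 3 tested genes fell (2 adjusted over the list alone), the synthase ICS1 at -1.77 (camera adjusted p = 0.33). Of 12 rapid touch and stress genes 1 rose (WRKY40, 1.92) and 3 fell (ERF5, ERF6 and CBF1), against 1 and 4 adjusted over the list alone (camera adjusted p = 0.34).

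Of 10 stem cell niche genes 1 rose, PLT3 at 0.85, also adjusted over the list alone (camera adjusted p = 0.95). Of 18 mitotic genes 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.52). Of 13 root hair genes 3 rose, led by RSL2 at 1.31 (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.68). Of 7 endodermal barrier genes 1 fell, also adjusted over the list alone, the Casparian strip gene CASP5 at -1.46 ± 0.12 (edgeR adjusted p = 2.2e-06, camera adjusted p = 0.054). Of 3 root cap genes BRN1 and BRN2 fell, at -0.73 and -0.64, also adjusted over the list alone (camera adjusted p = 0.26). No gene of the 7 in the xylem list passed, nor any adjusted over the list alone (camera adjusted p = 0.68). Of 4 phloem genes 2 rose (3 adjusted over the list alone), PP2-A1 at 1.21 and APL at 0.95, and the camera adjusted p = 0.025 became an adjusted p = 0.093 with an estimated correlation. None of 11 shoot photosynthesis genes or of 5 seed storage genes, markers of tissue other than root, passed in either form (camera adjusted p = 0.51 and 0.98).

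Without rescaling between libraries, FPKM values shifted the median gene by -0.05 in Col and -0.28 in erf114. The share of higher genes among the calls was 47.5% in Col and 54.2% in erf114 in edgeR, 32.7% and 22.6% with limma on those FPKM values, and 41.3% and 45.1% with limma after quantile normalisation. The last 2 settings changed the test as well as the scaling, while median-of-ratios scaling within edgeR gave 47.8% and 56%.

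**Figure D2:**
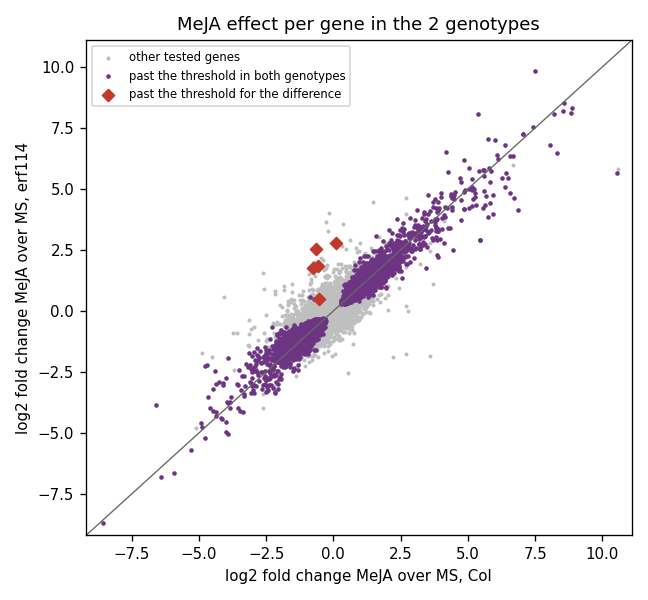
Log2 fold change of MeJA over MS in Col (x axis) against that in erf114 (y axis) for the 18326 tested genes, 1 point per gene. Purple points passed in both genotypes and red diamonds passed for the difference; points of genes with a group at or near 0 counts are fitted values, and Pearson's r across genes was 0.851.

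MeJA against MS in erf114 addressed the same response in the mutant. VSP2 rose from 2.22 ± 0.4 to 273 ± 15 FPKM, a log2 change of 7.25 ± 0.20 (edgeR adjusted p = 1.1e-09), and JRG21 rose by 8.31 ± 0.27 (edgeR adjusted p = 3.2e-09). NRT2:1 fell from 52.9 ± 3.1 to 1.17 ± 0.75 FPKM, a log2 change of -5.22 ± 0.33 (edgeR adjusted p = 3.6e-07). In all, 3438 genes changed, 1863 higher and 1575 lower. Of these, 1720 changed at least 2-fold, 1031 higher and 689 lower, and 5180 genes had an unadjusted p under 0.05. AT2G38240 (8.50 ± 0.48), CLH1 (8.13 ± 0.37), BGLU24 (8.05 ± 0.33) and AT3G19550 (6.81 ± 0.33) were among the largest rises. The tetraspanin TET11 was at least 42.1-fold, FLP1 at least 8.49-fold and AT5G35945 at least 6.02-fold higher, from no counts on MS, and PGL5 went from 2 to 557 counts. The largest falls also included AT5G44574 (-5.70 ± 0.51), AT5G01740 (-4.75 ± 0.25), AT3G46880 (-4.55 ± 0.28), AT3G45160 (-4.29 ± 0.30), UMAMIT17 (-4.13 ± 0.26), PHO1;H1 (-3.98 ± 0.28), MES13 (-3.73 ± 0.35) and bZIP3 (-3.72 ± 0.27).

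In the mutant 8 of 13 JAZ genes rose (9 adjusted over the list alone), with a median of 1.89 and JAZ3 at 2.49 ± 0.23. JAZ8 stood at 21 ± 23.4 FPKM on MS and 62.0 ± 33.7 on MeJA, a log2 value of 1.89 ± 0.82 that did not pass (edgeR adjusted p = 0.15). ERF109, at 67.2 ± 76.2 and 84.9 ± 49.6 FPKM, did not pass either (0.66 ± 0.75, edgeR adjusted p = 0.66). Without erf114 MS replicate 3 both passed, JAZ8 at 3.38 (edgeR adjusted p = 0.015) and ERF109 at 2.2 (edgeR adjusted p = 0.037). That library held a mean log2 level of 5.31 over the JAZ list, against 3.93 and 4.02 in the other erf114 MS libraries, and of 6.52 over the touch list, against 5.63 and 5.41. In JA biosynthesis 8 genes rose and 1 fell (11 and 1 adjusted over the list alone), with ACX1 at 1.86 ± 0.15. In JA catabolism 7 of 9 rose (7 adjusted over the list alone), with a median of 2.55. Camera gave adjusted p = 9.6e-07, 2.7e-06 and 1.4e-35 for these lists, and adjusted p = 0.1, 0.13 and 0.001 with an estimated correlation. All 5 MYC-branch genes rose (5 adjusted over the list alone, median 5.86, camera adjusted p = 2.6e-35, and 0.001 with an estimated correlation). In the receptor, MYC and JAM list 2 of 9 rose (4 adjusted over the list alone, camera adjusted p = 0.2), NINJA at 1.02 ± 0.09 and JAM1 at 2.28 ± 0.54. In the ERF-branch ERF1 rose by 1.70 ± 0.42, the defensin genes PDF1.2A and PDF1.2b rose from 0 counts on MS to 18 and 43, and ORA59 stood at -2.68 ± 0.29 (3 higher and 1 lower also adjusted over the list alone, camera adjusted p = 0.66). Of 6 group X genes 4 rose (5 adjusted over the list alone, camera adjusted p = 4.3e-09, and 0.015 with an estimated correlation). RAP2.6L rose by 2.92 ± 0.15, and ERF114 went from 2 to 36 counts, a ratio of 22.1 (95% counting interval 5.68 to 189).

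Of 15 indole glucosinolate genes in erf114, 13 rose and 1 fell on MeJA (13 and 2 adjusted over the list alone, median 1.70), with CYP81F4 at 2.57 ± 0.12. All 6 triterpene genes rose (6 adjusted over the list alone, median 3.01), with THAS1 at 4.10 ± 0.20. All 7 PYK10 and ER body genes rose (7 adjusted over the list alone, median 2.1). PYK10 itself stood at -0.05 with limma after quantile normalisation. That setting holds the highest ranks nearly equal between libraries, and PYK10 held the most counts of any gene in every erf114 library. The scaling ranks genes by FPKM and not by counts, so it may have hidden a rise of PYK10, which was not tested. Of 13 tryptophan and auxin biosynthesis genes 7 rose and 1 fell (8 and 3 adjusted over the list alone, median 1.16). Camera gave these lists adjusted p = 3.5e-28, 7.4e-28, 1.3e-21 and 3.4e-09, and 0.0012, 0.0012, 0.00023 and 0.0053 with an estimated correlation. Of 6 flavonoid genes 5 rose (6 adjusted over the list alone, median 1.16), including chalcone synthase CHS at 1.57 ± 0.23 and MYB12 at 0.57 ± 0.15, with a camera adjusted p = 2.9e-06 and an adjusted p = 0.082 with an estimated correlation. Aliphatic glucosinolate genes again moved apart, with 2 of 9 higher and 2 lower (2 and 2 adjusted over the list alone, median -0.03, camera adjusted p = 0.82). Iron uptake genes fell, 6 of 8 (7 adjusted over the list alone, median -2.34, camera adjusted p = 3.9e-09, and 0.038 with an estimated correlation), with FRO2 at -3.41 ± 0.30. Of 13 auxin response genes 5 fell and 1 rose (5 and 1 adjusted over the list alone, median -0.47), with a camera adjusted p = 0.0096 that was lost with an estimated correlation (adjusted p = 0.05, over the threshold before rounding).

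Of the 8 ethylene genes in erf114, 3 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.7), with ETR2 at 1.76 ± 0.21 (edgeR adjusted p = 7e-05). Regeneration genes (2 of 5 higher, 3 higher and 1 lower adjusted over the list alone) and phloem genes (3 of 4 higher, 4 adjusted over the list alone) had camera adjusted p = 0.038 and 0.044, and both lists had an adjusted p = 0.1 with an estimated correlation. CASP5 fell in the mutant too, at -1.74 ± 0.12, and was the only endodermal gene of 7 to pass. In the salicylic acid list ICS1 (-1.54 ± 0.38) and WRKY70 (-1.48 ± 0.40) fell. No gene of the stem cell niche, root hair, root cap, xylem, camalexin, shoot or seed lists passed in edgeR, and camera called no other list.

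**Figure D3:**
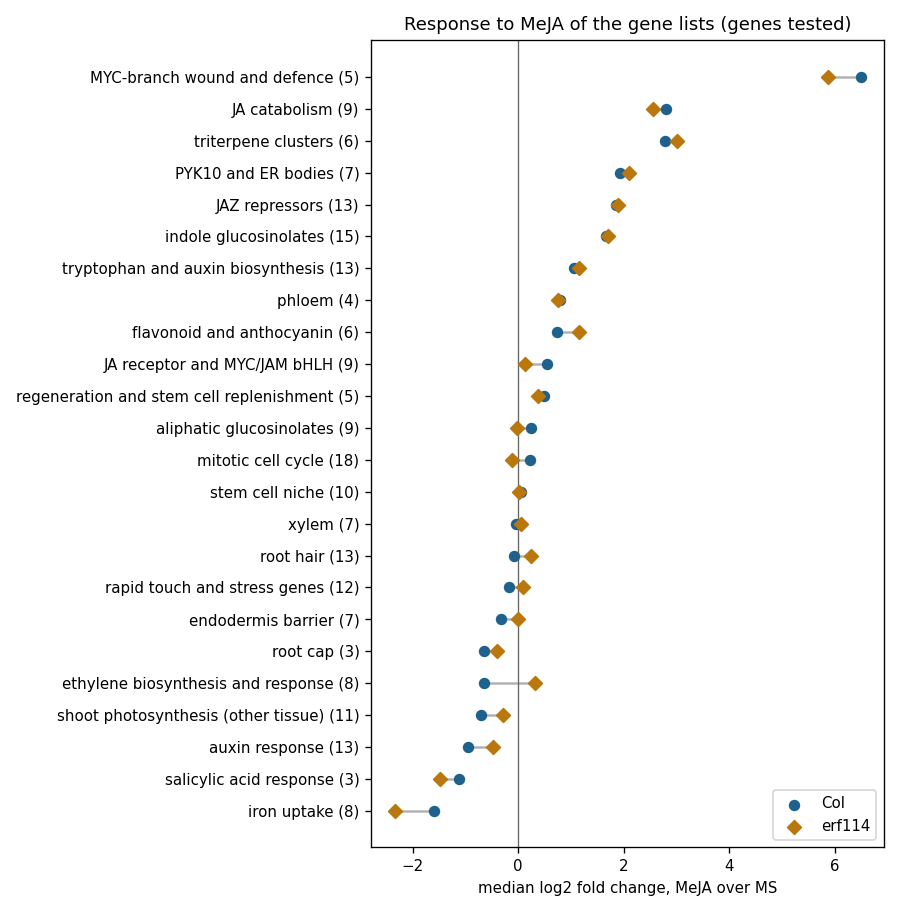
Median log2 fold change of MeJA over MS (x axis) of each gene list (y axis, number of genes tested in parentheses), with Col as blue circles and erf114 as orange diamonds. The 4 lists in which a gene had 3 or fewer counts in a group are left out, and the MYC-branch list lies farthest to the right, at 6.48 and 5.86.

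Most genes called in Col had the same sign in erf114. Across genes, which are not independent replicates, the MeJA effects of Col and erf114 correlated at Pearson's r = 0.851 and Spearman's rho = 0.578, with a slope of 0.798. These contrasts share no library. Of the calls, 1427 were higher in both genotypes against 194 for independent lists, 1184 were lower in both against 182, and 4 went opposite ways. Of the genes called in Col, 97.3% had the same sign in erf114. A response score over 1391 genes (690 higher and 701 lower in the mean of both genotypes) rose by 1.7 in Col and 1.634 in erf114. The difference of -0.066 missed the threshold (exact permutation test, p = 0.52). The SD of the score between replicates was 0.006 in Col and 0.137 in erf114 on MS, and 0.029 and 0.056 on MeJA. The wide spread on MS in erf114 came with replicate 3, and without that library the difference turned to 0.026. In simulated data a response 30% smaller in erf114 gave a score difference of -0.515. It missed the threshold too (exact permutation test, p = 0.07), so the p-value alone could not decide on a loss of that size. The measured difference of -0.066 was much smaller in size. With each library left out in turn it ran from -0.109 to 0.026. These values argue against a loss of 30% in the mean over the 1391 genes, not for each gene.

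erf114 against Col on MS addressed what the mutation changes in roots without added hormone, where ERF114 itself was at the limit of detection. AT2G44500 (chromosome 2, 18374162 to 18376799), annotated as an O-fucosyltransferase family protein, was higher in erf114, at 210 ± 7 against 41.9 ± 12 FPKM, a log2 difference of 2.25 ± 0.16 (edgeR adjusted p = 4.6e-05). AT4G29200 (annotated as beta-galactosidase related, chromosome 4, 14398054 to 14400198) was nearly silent in the mutant, with 4 counts against 2477 in Col, a Col to erf114 ratio of 663 (95% counting interval 259 to 2430). The orphan gene QQS (chromosome 3, 12349047 to 12349933), which modulates starch content, was at 0.39 ± 0.13 against 23.8 ± 1.9 FPKM, a log2 difference of -5.93 ± 0.30 (edgeR adjusted p = 1.6e-06). MRD1 (chromosome 1, 19963047 to 19964712) stood at -4.02 ± 0.57 (370 counts against 5413), the retroelement SADHU3-2 (chromosome 3, 14749400 to 14750294) at -2.57 ± 0.36, and the nicotianamine synthase NAS2 (chromosome 5, 22711141 to 22712441) at 1.21 ± 0.17, each at an edgeR adjusted p = 0.04. These 6 genes, 2 higher and 4 lower, were all that edgeR called, and 700 had an unadjusted p under 0.05. DESeq2 called 19. MRD1 overlaps an annotated antisense transcript whose reads could not be told apart, since use of strand is not stated.

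NAS2 and MRD1 did not pass with replicate number as a block (edgeR adjusted p = 0.083 and 0.091), and SADHU3-2 did not pass with only these 2 groups in the fit (0.61). Without erf114 MS replicate 1 the count was 16, and it was 3 without Col MS replicate 3, without erf114 MS replicate 3, or without any 1 of the 6 MeJA libraries.

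On MS no single gene of the fixed lists passed over all genes, and several lists shifted in camera. Triterpene genes were lower in erf114, with a median of -0.60, 5 of 6 lower adjusted over the list alone, and MRN1 at -1.26 ± 0.25 (camera adjusted p = 3.5e-13, but adjusted p = 0.077 with an estimated correlation). Iron uptake genes were higher, with a median of 0.70, 5 of 8 adjusted over the list alone, and FRO2 at 0.76 ± 0.27 (camera adjusted p = 1.7e-06, but adjusted p = 0.23 with an estimated correlation). MYC-branch genes (median 0.44, camera adjusted p = 0.024) were lost at adjusted p = 0.62 with an estimated correlation. Endodermal genes (median -0.28, 1 lower adjusted over the list alone, camera adjusted p = 0.0064) were lost at adjusted p = 0.48 with an estimated correlation. All 5 seed storage genes were higher in erf114 adjusted over the list alone (camera adjusted p = 2.3e-09, but adjusted p = 0.23 with an estimated correlation). Their mean log2 level was 3.02 to 4.01 in 5 of the 6 erf114 libraries, 0.03 in erf114 MS replicate 1, and 0.04 to 0.33 in Col. JAZ8 (0.27 ± 0.83) and ERF109 (0.66 ± 0.75) did not pass (edgeR adjusted p = 0.94 and 0.86).

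**Figure D4:**
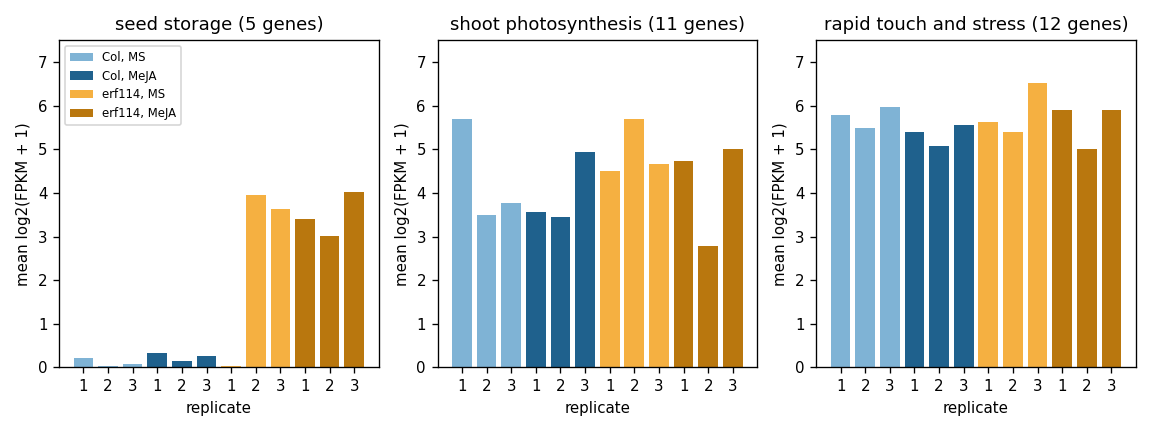
Mean log2 level (y axis) of the seed storage, shoot photosynthesis and rapid touch lists in each of the 12 libraries, with 1 bar per library, replicate number on the x axis and groups by colour. Seed storage transcripts reach 3.02 to 4.01 in 5 of the 6 erf114 libraries and stay at or below 0.33 in every Col library.

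erf114 against Col on MeJA addressed what the mutation changes under hormone, when ERF114 is expressed in Col. PDC1 (AT4G33070, chromosome 4, 15952257 to 15954803), a pyruvate decarboxylase of ethanolic fermentation, was higher in the mutant, at 113 ± 14 against 25.2 ± 5.2 FPKM, a log2 difference of 2.27 ± 0.19 (edgeR adjusted p = 0.00021). PDC1 also lay higher in erf114 on MS (0.80 ± 0.19), a difference that did not pass (edgeR adjusted p = 0.84). Its interaction did not pass either (edgeR adjusted p = 0.19). FTM1 (AT1G43800, chromosome 1, 16577521 to 16579722), a stearoyl-ACP desaturase, was at 36.1 ± 4.4 against 6.38 ± 1.1 FPKM (2.63 ± 0.27, edgeR adjusted p = 0.0011). ELIP1 (AT3G22840, chromosome 3, 8084405 to 8085669), an early light-induced protein, was at 71.4 ± 14 against 16.2 ± 0.5 FPKM (2.29 ± 0.25, edgeR adjusted p = 0.0015). The ethylene receptor ETR2 (AT3G23150, chromosome 3, 8254559 to 8257888) was at 16.2 ± 2.9 against 4.11 ± 0.54 FPKM (2.12 ± 0.22, edgeR adjusted p = 0.001). edgeR called 70 genes, 60 higher and 10 lower in erf114, of which 44 differed at least 2-fold, 38 higher and 6 lower. DESeq2 called 233, and 1572 had an unadjusted p under 0.05.

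Other genes higher in erf114 on MeJA were AT2G17850 (3.96 ± 0.60), the aquaporin NIP2;1 (2.81 ± 0.33), AT4G33560 (2.67 ± 0.47), AT2G39980 (2.49 ± 0.22), AT5G39890 (2.08 ± 0.30), a plant cysteine oxidase of oxygen sensing, and the retroelement SADHU5-1 (1.94 ± 0.31). Genes lower in erf114 were AT4G29200 (1 count against 1618, a ratio of 1490 with an interval of 268 to 59000), QQS (-4.93 ± 0.31), MRD1 (-3.12 ± 0.55), AAE17 (-0.85 ± 0.11), AT5G24870 (-0.67 ± 0.12), AT1G30820 (-0.64 ± 0.10) and CASP5 (-0.64 ± 0.12, edgeR adjusted p = 0.0499). AT14A and AT3G28300 both stood at -3.54 ± 0.22 with identical counts, 1580 in Col and 125 in erf114. They are near-identical neighbours whose reads cannot be told apart, so which copy differed is uncertain. Of the 6 genes called on MS, 5 were called on MeJA with the same sign, and across all genes the genotype effects on MS and MeJA correlated at Pearson's r = 0.364 and Spearman's rho = -0.205.

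**Figure D5:**
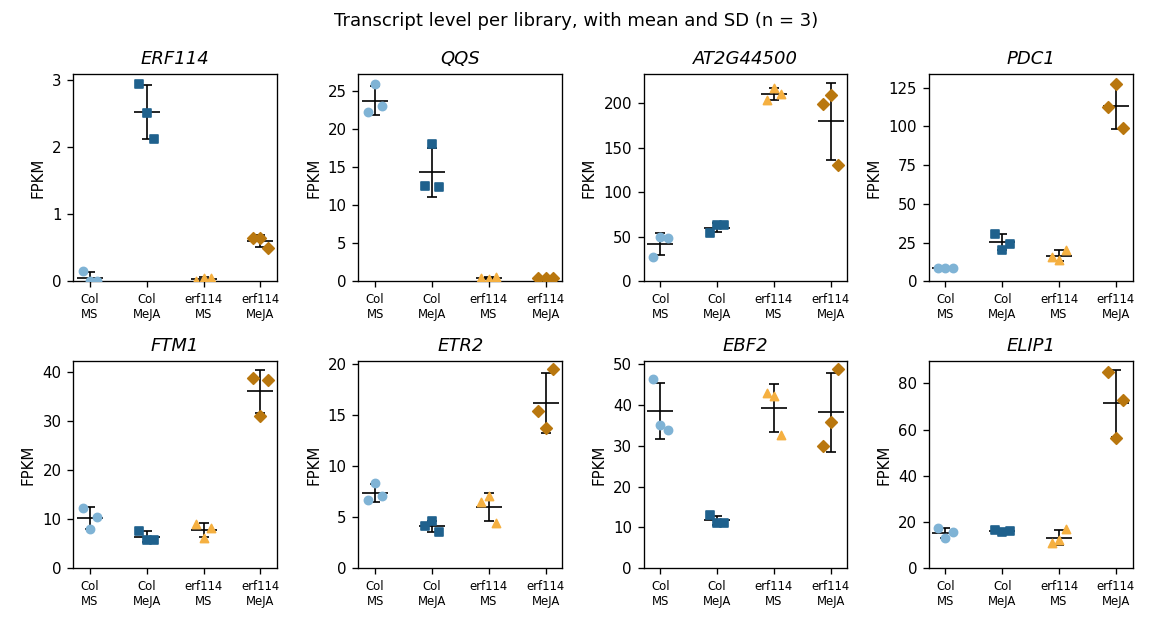
FPKM (y axis, 1 panel per gene) of selected genes in the 12 libraries, with 1 symbol per library, a line for the mean, whiskers for the SD (n = 3) and the 4 groups on the x axis. ERF114 is at 2.53 FPKM in Col and 0.60 in erf114 on MeJA and near 0 on MS.

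Ethylene genes were higher in erf114 on MeJA, with 3 of 8 called over all genes and 5 higher and 1 lower adjusted over the list alone, a median of 0.72 and camera adjusted p = 3.1e-11, which held at 0.02 with an estimated correlation. They were ETR2, the ACC oxidase ACO1 (1.00 ± 0.14) and the F-box gene EBF2 (1.84 ± 0.26). Flavonoid genes were higher too, with 2 of 6 called, MYB12 (1.06 ± 0.16) and the isomerase TT5 (0.85 ± 0.13), and all 6 adjusted over the list alone, a median of 0.87 and a camera adjusted p = 7.6e-12, with an adjusted p = 0.052 with an estimated correlation. In ERF group X RAP2.6L was called (0.74 ± 0.14, edgeR adjusted p = 0.044), with 3 higher and 1 lower adjusted over the list alone and a camera adjusted p = 0.097. Seed storage transcripts were present in all 3 erf114 libraries on MeJA, and the shoot photosynthesis list had mean log2 levels of 4.72, 2.78 and 5.0 there against 3.57, 3.45 and 4.94 in Col. JAZ8 (0.70 ± 0.79) and ERF109 (0.55 ± 0.75) did not pass (edgeR adjusted p = 0.79 and 0.82).

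Camera called 9 further lists on MeJA, none of which held with an estimated correlation. Auxin response (median 0.36, adjusted p = 0.0018, and adjusted p = 0.052 with an estimated correlation), MYC-branch (0.53, 0.0045, and adjusted p = 0.29 with an estimated correlation), indole glucosinolate (0.13, 0.03, and adjusted p = 0.46 with an estimated correlation) and touch genes (0.52, 0.018, and adjusted p = 0.61 with an estimated correlation) lay higher in erf114. The ERF-branch also lay higher (adjusted p = 0.00052, and adjusted p = 0.19 with an estimated correlation). So did the seed storage list (adjusted p = 1.4e-11, and adjusted p = 0.068 with an estimated correlation). The mean log2 level of the ERF-branch was 3.13 to 3.72 in the erf114 libraries that held seed storage RNA, on either medium. It was 2.69 in erf114 MS replicate 1, with almost no seed RNA, and 2.41 to 2.71 in Col. The ERF-branch shift thus went with seed RNA, and whether seed remains carried it was not tested. Aliphatic glucosinolate (-0.18, 0.014, and adjusted p = 0.25 with an estimated correlation), triterpene (-0.34, 0.0021, and adjusted p = 0.3 with an estimated correlation) and mitotic genes (-0.21, 0.00093, and adjusted p = 0.091 with an estimated correlation) lay lower. Adjusted over the list alone, the calls were VSP1, IAA14 and CYP81F4 higher, MAM1 lower, the ERF-branch genes PR3 and PDF1.1 higher, 3 triterpene genes lower and all 5 seed storage genes higher.

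The count of 70 depended on single libraries. It was 133 without Col MS replicate 1, 41, 19 and 19 without Col MeJA replicates 1, 2 and 3, and 35 and 42 without erf114 MeJA replicates 1 and 3.

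The interaction of genotype and treatment addressed whether the MeJA response itself differs in erf114. It was called for 5 genes, all more positive in erf114. FTM1 was at -0.64 ± 0.27 in Col and rose by 2.53 ± 0.27 in erf114, a difference of 3.18 ± 0.38 (edgeR adjusted p = 0.021). ELIP1 differed by 2.65 ± 0.34 (edgeR adjusted p = 0.022). ETR2 fell in Col and rose in erf114, a difference of 2.54 ± 0.30 (edgeR adjusted p = 0.021). AT2G39980 (chromosome 2, 16687673 to 16690182) differed by 2.39 ± 0.30 and AT1G77330 (chromosome 1, 29062945 to 29064637), an ACC oxidase-like gene, by 1.03 ± 0.13 (edgeR adjusted p = 0.022 for both). DESeq2 called 43 genes, and 1107 had an unadjusted p under 0.05. The ERF114 (-1.35 ± 1.62), JAZ8 (0.43 ± 1.14) and ERF109 (-0.11 ± 1.05) interactions did not pass (edgeR adjusted p = 0.72, 0.87 and 0.97).

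Among the lists, the ethylene list had a median interaction of 0.53 (1 called over all genes and 2 adjusted over the list alone, camera adjusted p = 6.9e-06, but adjusted p = 0.13 with an estimated correlation). The flavonoid list had 0.61 (2 adjusted over the list alone, MYB12 and CHS, camera adjusted p = 4.6e-05, but adjusted p = 0.34 with an estimated correlation). Camera did not separate the JAZ list (adjusted p = 0.84) or JA catabolism (0.82) between the genotypes. The count of 5 fell to 0 in edgeR without Col MS replicate 3, without any 1 of the Col MeJA libraries, without erf114 MS replicate 1 or 2, or without erf114 MeJA replicate 1. It was 2 without erf114 MS replicate 3, 1 without erf114 MeJA replicate 3 and 8 without erf114 MeJA replicate 2.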

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

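The tests on seed remains, on the ERF114 transcript and on linked DNA were chosen after the result was seen.

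The MeJA effect differed between the genotypes by the interaction test for 5 genes, 3.18 for FTM1, 2.65 for ELIP1, 2.54 for ETR2, 2.39 for AT2G39980 and 1.03 for AT1G77330 on the log2 scale. By camera it differed for the flavonoid and anthocyanin list, with a median difference of 0.61, and for the ethylene list, with 0.53, though both calls were lost with an estimated correlation. Of 100 drawn splits of the libraries by genotype within treatment, the real one included, 7 called at least 5 genes. Of the other 6, 5 left the genotypes unmixed on MS or on MeJA, so that a real genotype difference there entered them, and of the 75 that mixed the genotypes on both media 1 called as many. These splits therefore leave open whether chance can be excluded for the 5 genes. The highest of the other splits called 208 genes, against 5 in the real one, and mixed the genotypes on both media. It took Col MS replicates 1 and 3, Col MeJA replicates 2 and 3, erf114 MS replicate 3 and erf114 MeJA replicate 2 as Col. A structure of the samples other than genotype may lie behind that count, which was not tested.

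The 60 genes higher in erf114 than in Col on MeJA came with seed storage RNA in 5 of 6 erf114 libraries and with unequal shoot RNA. Seed remains that carry these transcripts whatever the treatment were argued against for the 60 genes as a set, not for each gene. erf114 MS replicates 2 and 3, with as much seed RNA, showed a median share of 0.16 of the MeJA difference (bootstrap interval over genes 0.12 to 0.21, 10000 draws). In erf114 MS replicate 1, with almost no seed RNA, the median share was 0.17. The genes had been called on that difference, which lowers the share, and single genes may differ. Unequal shoot tissue was excluded as the whole cause, since with the shoot level as a covariate the genes kept 99.6% of their median log2 difference (1.31 before and after) and all 60 stayed called. A candidate biological explanation is a higher level of low-oxygen transcripts in erf114, drawn from 11 low-oxygen genes seen among the calls. Another 13 low-oxygen genes, not looked at before, had a median difference of 0.97, all 13 above 0 (camera p = 0.0053 with an estimated correlation). edgeR called none of the 13 over all genes. The 13 came from the same libraries as the 11, so they are not independent support. Some rested on erf114 MeJA replicate 1, such as SRO5 at 159.7, 46.26 and 68.27 FPKM, against 84.32, 39.72 and 69.37 in Col. Others did not, such as AT3G03270 at 112.78, 135.37 and 107.16 against 80.35, 53.64 and 62.19. The 13 were not tested with single libraries left out. A stronger response of these 13 genes to MeJA in erf114 was neither shown nor excluded. Of the 13, 12 lay above 0 on MS (median 0.37) and 12 for the interaction (median 0.6). Their median MeJA effect was 1.14 in erf114 and -0.27 in Col. Camera with an estimated correlation missed the threshold for the interaction (p = 0.16) and for MeJA in erf114 (p = 0.43). An effect of the mutation, a difference in how the plates were handled or aired and seed remains that respond to MeJA stay open and untested.

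The 6 genes called between the genotypes on MS were set against the ERF114 transcript and against DNA linked to the mutated locus. Whether the ERF114 transcript present at sampling set them could not be decided, since ERF114 had 3 counts over the Col MS libraries and 2 over the erf114 MS libraries, too few to compare. Linked DNA was excluded as the cause for most of them, since 1 of the 6, NAS2 at 2.14 Mb from ERF114, lay within 5 Mb of it. A candidate explanation that was not tested is that the Col and erf114 lines had drifted apart. Methylation of QQS and SADHU3-2, which could differ between lines, was not measured here. ERF114 acting before sampling stays open too.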

How the results depend on the processing

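DESeq2, the length and GC correction and the block combined with other choices were chosen after the data were seen. So was the fit without both Col MS replicate 1 and erf114 MeJA replicate 3. limma on log2(FPKM + 1) had been fixed beforehand as the test for FPKM tables, and its use beside edgeR was added after the data were seen. Over 318 named gene results and their settings, 7691 values kept direction and side of the threshold, 487 were weaker, 4 stronger and 15 reversed. For 47 list results 732 were the same and 67 weaker. AT2G44500, AT4G29200 and QQS kept their calls on MS under every setting. For MeJA in erf114 the count of 3438 moved over 1.5 times, to 5419 genes with limma on log2(FPKM + 1) and 5352 with limma and a pseudocount of 0.1, both with 22.6% higher against 54.2%. The settings with a pseudocount or quantile scaling used limma and so changed the test too. Counts stayed within 1.5 times in Col, at 4620 (32.7% higher) and 4573 (32.8%) against 4026 (47.5%), and with limma after quantile scaling, at 4855 (41.3%) in Col and 4024 (45.1%) in erf114. DESeq2 called 19 genes on MS, 233 on MeJA and 43 for the interaction, and the fit with only the groups compared called 3 on MS. Without that pair of libraries edgeR called 0 interaction genes, against 5 with all 12, where 1107 genes had an unadjusted p under 0.05 and DESeq2 called 43. Without the filter the correlation of MeJA effects was 0.6. With an estimated correlation 17 list calls held of 47. The ERF114 difference on MeJA (-1.95, adjusted p = 0.071) passed with limma after quantile scaling (-1.06, 0.0047), only the groups compared (-1.96, 0.029), DESeq2 (-1.95, 0.00056), limma on log2(FPKM + 1) (-1.14, 0.0018) and the length and GC correction (-1.97, 0.05, under the threshold before rounding), and without Col MS replicate 1 (0.014). The cause was not tested.

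Leaving out each library gave 2814 to 4371 genes for MeJA in Col, 2587 to 4109 in erf114, 3 to 16 on MS, 19 to 133 on MeJA and 0 to 8 for the interaction, the libraries being named with the counts above. The correlation ran from 0.779 to 0.897, the score difference from -0.109 to 0.026, ERF114 from -2.07 to -1.78 and the list calls from 45 to 58. Values that reversed were PYK10 for MeJA in erf114 at -0.05 with limma after quantile scaling; JAZ8 on MS at -0.2 without Col MS replicate 2 and -1.21 without erf114 MS replicate 3 (range over single libraries to 1.39); ERF109 on MS at -0.88 without erf114 MS replicate 3 (range to 1.11); ERF114 on MS at 2.56 without Col MS replicate 1 (range from -1.2) and 2.58 without that pair; ERF109 on MeJA at -0.01 without erf114 MeJA replicate 1 (range to 0.88); the JAZ8 interaction at -0.68 without Col MS replicate 1, -0.03 without erf114 MS replicate 1, -0.06 without erf114 MeJA replicate 1 and -0.66 without that pair (range over single libraries to 1.91); the ERF109 interaction at 0.29 without Col MS replicate 2, 0.12 without Col MeJA replicate 3, 1.42 without erf114 MS replicate 3 and 0.23 without erf114 MeJA replicate 2; and the score at 0.026 without erf114 MS replicate 3. Quantile scaling holds the highest ranks nearly equal between libraries and may have hidden a rise of PYK10, which was not tested. ERF114 on MS had 3 counts in Col and 2 in erf114, too few for its reversed values to be read. For the other reversed values the cause was not tested either. The replicate block gave 4405 genes for MeJA in Col (5339 with only those groups), 4 on MS (9 with only those groups), 3674 for MeJA in erf114, 87 on MeJA and 6 for the interaction. The numbers did not pair MeJA with MS in erf114 (-0.23, 0.11 and -0.29) or the genotypes on MeJA (0.09, 0.4 and -0.21). The fit without both erf114 MS replicates 2 and 3 was not run, since 1 library would remain. Depth limits ERF114, ERF115 and other genes of few counts.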

Other observations

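The tests on length, GC and shoot tissue in Col MS replicate 1 and the genes named here outside the fixed lists were chosen after the result was seen.

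Genes called higher in erf114 on MeJA also included several that were picked after their values were seen and not tested as a group. STO, a B-box protein of light signalling, differed by 0.96 ± 0.12 on the log2 scale (edgeR adjusted p = 0.0051), STH by 1.35 ± 0.20, BBX28 by 1.48 ± 0.26 and the early light-induced gene ELIP2 by 1.92 ± 0.28. The sinapate glucosyltransferase UGT84A2 differed by 1.58 ± 0.20 and the flavonoid glucosyltransferase UGT78D2 by 0.96 ± 0.16. BBX28 fell from 13.2 ± 1.5 to 4.27 ± 0.52 FPKM on MeJA in Col and stood at 10.5 ± 1.5 and 10.8 ± 3.0 FPKM in erf114, an interaction that did not pass (edgeR adjusted p = 0.19). KAI2, the karrikin receptor, was at 37.3 ± 3.4 FPKM in erf114 against 22.7 ± 1.4 in Col on MeJA. IAA28 differed by 0.71 ± 0.13.

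HB1, a non-symbiotic haemoglobin, differed on MeJA by 1.58 ± 0.22 and the sucrose synthase SUS4 by 1.61 ± 0.25, with PDC1. On MS every erf114 library also lay above every Col library for HB1 (0.82 ± 0.21), PDC1 (0.80 ± 0.19) and SUS4 (0.25 ± 0.25). These differences did not pass (edgeR adjusted p = 0.85, 0.84 and 0.85). Nor did the interactions of HB1, PDC1 and SUS4 (edgeR adjusted p = 0.64, 0.19 and 0.63). All 11 low-oxygen genes already seen among the calls had a median difference of 2.08. In camera with an estimated correlation the 13 genes not seen before missed the threshold on MS (median 0.37, p = 0.14) and for the interaction (median 0.6, p = 0.16). The 11 genes, which had been picked from the calls, passed in camera with an estimated correlation on MS (p = 0.046).

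Col MS replicate 1 lay apart from the other libraries of its group, with a mean squared log2 deviation from the other replicates of 0.349, against 0.166 and 0.099 for these. In erf114 on MeJA that value was 0.12, 0.239 and 0.218, with no single library set apart. Removing a length and GC trend took away 28.7% of the deviation of Col MS replicate 1, which neither makes it the main cause nor excludes it. The shoot slope of the other 11 libraries went with 34.5% of it, and with 10.9% when erf114 MeJA replicate 3 was also left out of the slope, so more shoot tissue stays open too. No biological explanation was tested, and a difference in handling stays open.

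For the contrasts of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split, 1 of the 10 in each contrast, called 4026, 3438, 6 and 70 genes, and the highest of the other splits called 0, 0, 0 and 3.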
